A study of Mus musculus with 2 samples.

How the data were processed

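Tumour tissue of 2 mouse liver cancer models was dissociated, live cells were enriched, and droplet-based 3 prime single-cell RNA libraries were sequenced, 1 library per model, per the labels' protocols. The deposited files hold raw UMI counts per gene and cell barcode, made with Cell Ranger against mm10, per the submitters' processing notes; the file header names version 6.1.1 and the notes name 6.1.2. The annotation release is not given in the sources used here. The files list 55450 genes with Ensembl identifiers and symbols, the same in both libraries, and no barcode holds fewer than 500 UMIs. Coordinates were taken from GENCODE vM21 on GRCm38 by identifier for the genes described in most detail.

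Cells with at least 500 UMIs, at least 250 detected genes and at most 20% mitochondrial UMIs were kept. This removed 351 barcodes of NRAS.MYC.ND and 456 of AKT1.MYC. Doublets were scored per library with Scrublet as built into Scanpy, at an expected rate of 0.8% per 1000 barcodes. Its automatic threshold marked 0.168% and 0.00970% of cells, under the 0.5% minimum set in advance, and so failed; the highest scores up to the expected rate, ties included, were removed instead, 327 and 913 cells. Kept cells held 38004526 and 60289235 UMIs, and 5.27% and 26.3% of them held fewer than 1000.

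Both libraries were clustered together without batch integration: counts scaled to 10000 per cell and log-transformed, 2000 variable genes, 30 principal components after clipping at 10, 15 neighbours and Leiden clustering at resolution 1.0 with seed 0. A cluster was called X-like where at least 3 markers of a type, out of lists for 27 types, were at least 2-fold higher in it than elsewhere and seen in at least 10% of its cells, and stayed unnamed where genes of another class led its top 10 genes. Of 245 markers, 243 matched a symbol in the files. Clusters were joined to classes, and classes with at least 50 cells in each library were compared. Sub-clusters of the lymphoid and myeloid classes separated almost wholly by library, so cells were instead gated by UMIs of T receptor, Cd8, Cd4, NK and Kupffer genes, a choice made after seeing the data.

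Per class and library, UMIs were summed and expressed as CPM of the class sum, with exact Poisson intervals. Ratios of counts have exact conditional binomial intervals and shares of cells exact Clopper-Pearson intervals, all at 95%. With 1 library per group, no test, p-value or count of changed genes was made from cells. A value of 0 was given the limit that 3 counts allow, and no ratio was formed where 1 library had 0 and the other did not exceed that limit, a rule chosen after seeing the data. In 38 gene lists, whose 596 members all matched a symbol, a member was measured with at least 10 UMIs over both libraries, and called higher in a library at 2-fold or more. A list median was set against 10000 random lists matched on expression in 20 bins, and its percentile describes these libraries only. Shares of cells with a UMI were computed with every cell thinned to the 10th percentile of UMIs of its class.

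Genes were named by a fixed rule: at least 50 CPM in the higher library, at least 30 UMIs over both, at least 0.5 times the level over all kept cells of that library, and among the largest ratios with an interval excluding 2-fold, up to 10 per direction in the hepatocyte-lineage, mononuclear phagocyte and T, NK and ILC classes and up to 5 elsewhere. Members of the gene lists were added. Mitochondrial, ribosomal protein, haemoglobin, sex-linked check, receptor segment and unnamed genes were left out. The lists covered MAPK output, fatty acid synthesis, glycolysis, cholesterol synthesis, MYC targets, oncofetal genes, liver functions, p53, hypoxia, chemokines, antigen presentation, interferon response, early response, macrophage, neutrophil, T cell, checkpoint, B cell, endothelial, fibroblast and proliferation genes, the injected loci, a marker panel and library checks.

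The filters, lists, markers, naming rule and other settings listed next were chosen before the data were examined. These settings covered the mitochondrial limit, depth filter, doublet removal, resolution, variable genes, clustering each library alone, median of ratios and upper quartile scaling, equal weight per cell, thinning, subtraction of free RNA and the UMI minimum of list members. Comparisons within the CD8 gate, in Kupffer-like clusters, in neutrophil-like sub-clusters, over all epithelial cells and with 0 counts kept at their limit were added after seeing the data.

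The ratio and interval steps were tested on simulated Poisson counts drawn from real class means. Each comparison had 50 changed genes at each of 4 folds, all at 50 CPM or more before the change. The intervals assume the same counting error, so this checks the computation only. The simulation held no variation between cells or libraries and no free RNA. It did not test the filters, doublet calls, clustering or naming. In mononuclear phagocytes (12207 genes) 100% of genes changed 0.25-, 0.5-, 2- or 4-fold had an interval excluding 1 on the right side, and in epithelial cells (14669 genes) likewise 100% at each fold. In T, NK and ILC cells (9457 genes) it was 88% at 0.5-fold and 100% at 0.25-, 2- and 4-fold. Intervals held the true ratio for 95.6%, 95.97% and 96.6% of genes. Python 3.11.15, Scanpy 1.11.5, anndata 0.12.19, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and Matplotlib 3.10.9 were used.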

Results

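Liver tumours of 2 models were profiled by droplet single-cell RNA sequencing, with 1 library per group. In the NRAS.MYC.ND group, liver cells had been transfected through the tail vein with plasmids for human N-Ras and human c-Myc, and in the AKT1.MYC group with plasmids for Akt1 and c-Myc, each with a transposase that inserts the oncogenes into the genome. The NRAS.MYC.ND group received 19 ug of N-Ras, 1 ug of c-Myc and 2 ug of transposase plasmid. The AKT1.MYC group received 10 ug of Akt1, 10 ug of c-Myc and 5 ug of transposase plasmid, so plasmid amounts differed along with the oncogenes. Tumours were taken 14 weeks after injection. The NRAS.MYC.ND library held 6312 cell barcodes and 42416125 unique molecular identifiers (UMIs), and the AKT1.MYC library 10766 barcodes and 64516171 UMIs. After filtering, 5634 and 9397 cells were kept, with medians of 4240 and 1987 UMIs. The value of NRAS.MYC.ND is given first in each pair, levels are CPM (the share of a gene in the UMIs of a cell class, in parts per 1e6), and log2 ratios are AKT1.MYC over NRAS.MYC.ND, so a negative ratio is a higher level in NRAS.MYC.ND. No difference has a replicate check, and the 95% intervals in parentheses cover counting error only, not the choice of settings. Most clusters came almost wholly from 1 library, and such a cluster may be a property of that library and not a cell type.

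At the mouse loci, Nras and Akt1 were each higher in the group injected with that gene. Nras (ENSMUSG00000027852; GRCm38 chromosome 3, 103058285 to 103067914) stood at 302 against 70.9 CPM over all kept cells and at 1588 against 65.6 CPM in hepatocyte-lineage cells, 24.2-fold higher in NRAS.MYC.ND. In mononuclear phagocytes Nras stood at 74.7 against 73.5 CPM, a log2 ratio of -0.02 that turned to 6.47 with free RNA subtracted. The subtraction took 24.5% of the profile of all kept NRAS.MYC.ND cells, where Nras stood at 302 CPM. It thus removed nearly all Nras of these phagocytes, and 6.47 does not show a higher level in AKT1.MYC. Akt1 (ENSMUSG00000001729; chromosome 12, 112653821 to 112674884) was higher in AKT1.MYC, with 48.6 against 159 CPM in hepatocyte-lineage cells and 58.7 against 252 CPM over all epithelial cells. In endothelial cells it stood at 189 against 175 CPM, so the level in AKT1.MYC hepatocyte-lineage cells does not show that they carried the plasmid. Myc (ENSMUSG00000022346; chromosome 15, 61985391 to 61990374), injected in both groups with 1 and 10 ug of plasmid per mouse, stood at 48.8 against 72.7 CPM over all kept cells, higher in AKT1.MYC, but at 153 against 69.9 CPM in hepatocyte-lineage cells and 138 against 111 CPM in epithelial cells. In cholangiocyte-like cells, of which NRAS.MYC.ND held 44, Myc stood at 16.8 against 112 CPM. Its epithelial value thus depends on the mix of the 2 classes. The labels call N-Ras and c-Myc human, so an unknown part of the transgene reads could map to these mouse protein-coding genes. Whether the Akt1 plasmid is human or mouse is not given in the sources used here. The median ratio of the 3 loci was -1.13 in hepatocyte-lineage cells, -0.32 in epithelial cells, -0.49 in endothelial cells, -0.43 in conventional dendritic cells (DCs), -0.42 in fibroblasts, -0.31 in T, NK and innate lymphoid (ILC) cells, -0.08 in mononuclear phagocytes and 0.23 in neutrophils and was not computed in erythroid cells.

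**Figure D1:**
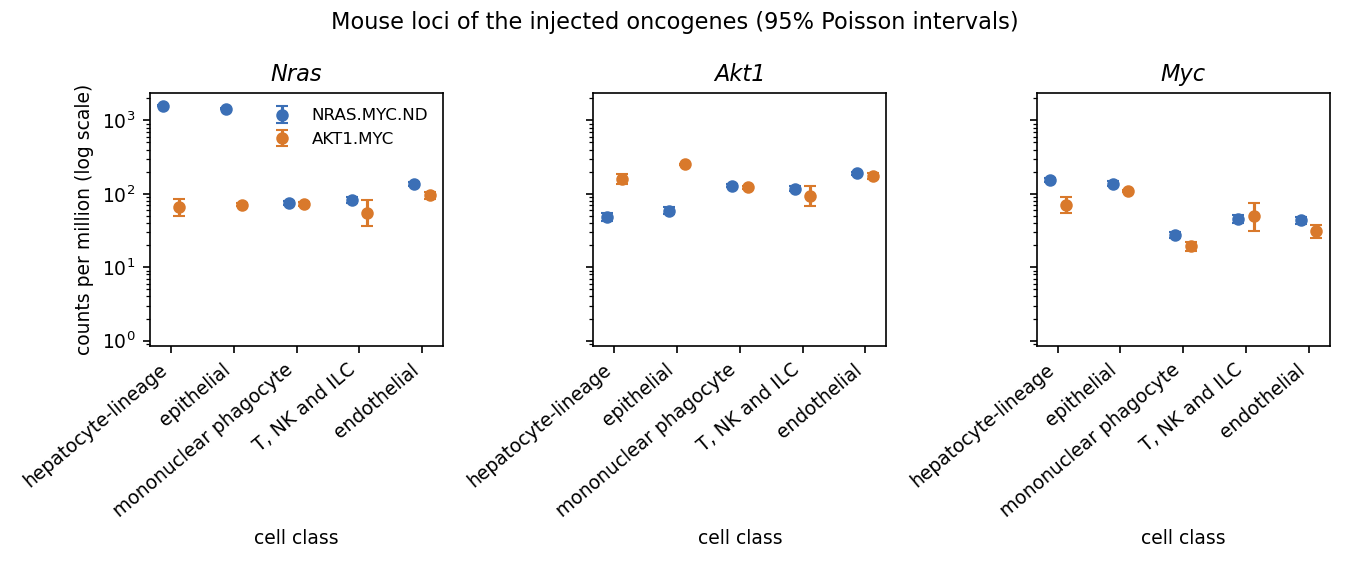
Levels of the mouse loci Nras, Akt1 and Myc in CPM (log axis) in 5 cell classes, with bars for exact 95% Poisson intervals of counting error. Nras in epithelial cells stood at 1450.4 against 70.96 CPM and Akt1 at 58.7 against 252 CPM in NRAS.MYC.ND and AKT1.MYC.

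The first comparison asked which immune cells the tumours of each model held, the subject of the series. T, NK and ILC cells were 37.2% (35.8 to 38.7) against 3.49% (2.95 to 4.09) of immune cells, 10.7-fold higher in NRAS.MYC.ND. B and plasma cells, the antibody lineage, were 8.28% (7.46 to 9.17) against 0.860% (0.603 to 1.19). Conventional DCs, which prime T cells, were 7.22% (6.45 to 8.05) against 1.72% (1.35 to 2.16). Plasmacytoid DCs, a source of type I interferon, were 49 cells in NRAS.MYC.ND and 0 of 4184 immune cells in AKT1.MYC, which allows up to 0.0717%. Neutrophils were a larger share in AKT1.MYC, 7.41% (6.63 to 8.25) against 26.03% (24.7 to 27.4), as were mononuclear phagocytes (monocytes, macrophages and Kupffer cells), 38.7% (37.2 to 40.2) against 67.9% (66.5 to 69.3). Immune cells together were 73.3% against 44.5% of kept cells. As shares of all kept cells, T, NK and ILC cells were 27.3% against 1.55%, B and plasma cells 6.07% against 0.383%, conventional DCs 5.29% against 0.766%, neutrophils 5.43% against 11.6% and mononuclear phagocytes 28.3% against 30.2%. When each library was clustered alone, conventional DCs turned to a log2 ratio of 0.46 as a share of immune cells and stood at -0.22 as a share of kept cells. Clusters left unnamed held 1.17% against 18.2% of kept cells, nearly all of the latter in 1 cluster of low depth.

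**Figure D2:**
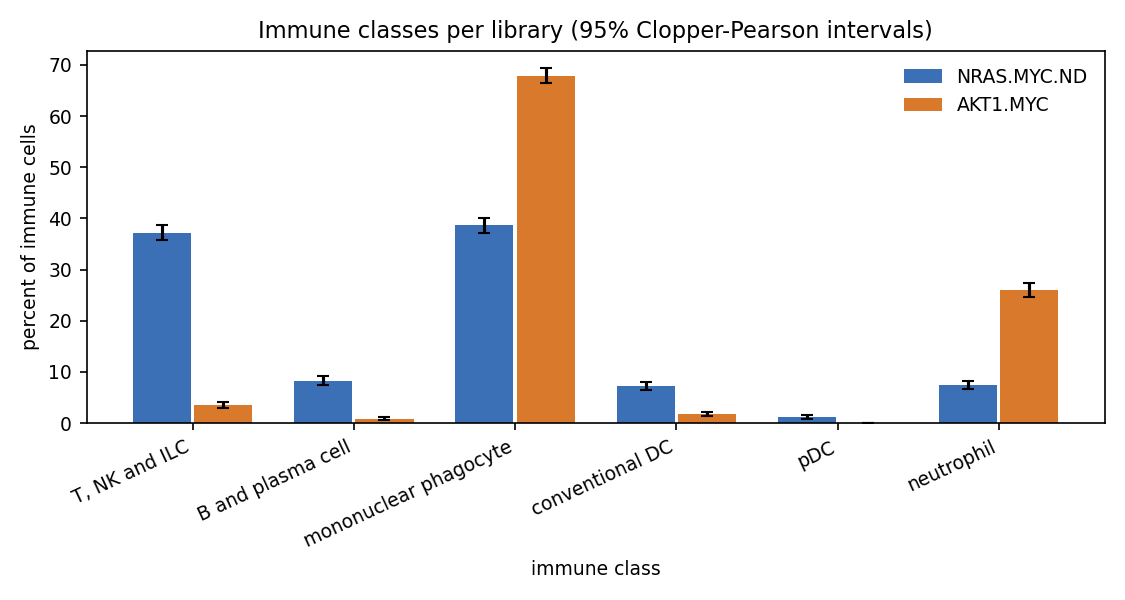
Percent of immune cells in 6 immune classes per library, with bars for exact 95% Clopper-Pearson intervals of counting error. T, NK and ILC cells were 37.2% against 3.49% and neutrophils 7.41% against 26.03% in NRAS.MYC.ND and AKT1.MYC.

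Within the T, NK and ILC class, Cd8 genes were more frequent in NRAS.MYC.ND and NK genes in AKT1.MYC. With every cell thinned to 1557 UMIs, which left out 135 and 34 cells, 64.6% (61.98 to 67.1) against 29.5% (20.6 to 39.7) of cells with a T receptor gene had Cd8a or Cd8b1 without Cd4 (not thinned, 69.6% against 34.4%). The mirror gate, Cd4 without either Cd8 gene, held 2.46% against 3.16%, and a gamma-delta constant gene (Trdc or a Tcrg-C gene) was seen in 15.5% against 12.6%. When the class was clustered again, a CD8 T cell-like sub-cluster of 298 NRAS.MYC.ND cells had Tcrg-C2 among its top 10 genes and Trdc at 0 CPM. This gate thus does not give the share of gamma-delta T cells. An NK gene was seen in 8.84% (7.40 to 10.4) against 26.8% (18.9 to 35.98) of the class (not thinned, 12.2% against 29.5%), and in mononuclear phagocytes, which should lack it, in 0.0703% against 0.102%. An NK gene without a T receptor gene was seen in 1.14% against 9.82%. A T receptor gene was seen in 98.6% against 84.8% of the class and, as free RNA, in 7.67% against 0.968% of mononuclear phagocytes. NRAS.MYC.ND cells of the class lay in CD8 T cell-like cluster 5 (922 cells) and T cell-like cluster 10 (485), and AKT1.MYC cells in NK cell or ILC1-like cluster 22 (138 of 146), so the gene levels that follow compare different mixtures. Clustering the class again named 75 NRAS.MYC.ND cells (4.88%) and 0 AKT1.MYC cells NK cell or ILC1-like and left 95.9% of the latter unnamed. The label of cluster 22 thus does not show that its AKT1.MYC cells were mostly NK cells.

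Inhibitory receptors and the exhaustion regulator Tox were higher in NRAS.MYC.ND in this class. Lag3 (ENSMUSG00000030124; chromosome 6, 124904361 to 124911705), a receptor that restrains T cells, stood at 390.2 against 21.4 CPM (log2 ratio -4.19), Tox at 431 against 49.2 (-3.13), its relative Tox2 at 70.8 against 8.56 (-3.05) and the receptor Havcr2 at 82.9 against 12.8 (-2.69). The residency chemokine receptor Cxcr6 (416 against 66.3 CPM), the folate receptor-like gene Izumo1r (69.99 against 6.42; log2 ratio -3.45, -5.73 to -1.89) and the signalling adaptor Sh3bp1 (74.1 against 8.56) were higher too. In thinned cells, Lag3 was seen in 34.1% against 5.36% of cells and Tox in 44.98% against 8.04% (not thinned, 44.9% against 6.16% and 59.8% against 12.3%), with 1.62% against 0.866% and 0.281% against 0.153% in mononuclear phagocytes. The receptor Pdcd1 was seen in 25.3% against 21.4% of thinned cells (0.0703% against 0.0509% in mononuclear phagocytes) and 36.7% against 21.2% of cells not thinned, and stood at 209.6 against 186 CPM. In the exhaustion and checkpoint receptor list, 13 of 16 measured members were at least 2-fold higher in NRAS.MYC.ND and 0 in AKT1.MYC, Ctla4 (346 against 109 CPM) among them, with a median log2 ratio of -1.54 (-1.90 to -1.32), at percentile 0 of random lists matched on expression. The median was -1.78 (-2.14 to -1.32) in the 1048 and 44 cells of the CD8 gate. Cd3e (1924 against 304 CPM) separates T from NK cells and served in naming, and Kng1, Aldh1a1 and Trem2 passed the naming rule but stood higher in epithelial cells or phagocytes of the same library, as free RNA does.

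Cytotoxic genes went both ways between the libraries. Granzymes Gzma (871 against 2966 CPM) and Gzmc (2.32 against 34.2), the granzyme inhibitor Serpinb9 (64.6 against 250.4) and the NK receptors Klra8 (7.54 against 55.6, a naming marker) and Klrb1b (16.6 against 105) were higher in AKT1.MYC. In thinned cells Gzma stood at 807 against 1652 CPM. It was seen in 15.4% (13.5 to 17.4) against 24.1% (16.5 to 33.1) of them, with overlapping intervals. Gzmk (491 against 92.02), the chemokine Ccl5 (30855 against 8535), Nkg7 (2658 against 1079) and interferon gamma, Ifng (419 against 205), were higher in NRAS.MYC.ND. Ifng was seen in 35.2% against 16.96% of thinned cells (not thinned, 48.4% against 24.7%) and 0.492% against 0.0509% of mononuclear phagocytes. The cytotoxicity list thus had 3 members higher in AKT1.MYC, 6 in NRAS.MYC.ND and 8 in neither (median -0.37; -0.71 (-1.15 to -0.44) in the CD8 gate). Of the naive and memory list, 4 members were higher in AKT1.MYC and 1 in NRAS.MYC.ND, among the former Satb1 (58.8 against 154 CPM) and Ccr7 (42.5 against 85.6); the median was 0.03 in the class and 1.04 (0.59 to 1.40) in the CD8 gate. Medians were -0.501 (-0.75 to 0.09) for tissue residency and -0.12 (-0.46 to 0.31) for regulatory T activation, and each took both signs over the alternative settings. Of the tissue residency list, Prdm1 (74.6 against 17.1) was higher in NRAS.MYC.ND. Of the regulatory T list, Ikzf2 (192 against 59.9) was higher in NRAS.MYC.ND and Il2ra (4.25 against 25.7) in AKT1.MYC. Calca (4.83 against 74.9), the heat-shock gene Hspa1a (52.01 against 439) and the lipid enzyme Dgat1 (16.4 against 103) also led in AKT1.MYC.

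In mononuclear phagocytes, Kupffer identity, class II presentation and interferon response genes were higher in NRAS.MYC.ND and hypoxia genes in AKT1.MYC. Cxcl9 (ENSMUSG00000029417; chromosome 5, 92321347 to 92328079), which attracts T cells, stood at 379.6 against 16.9 CPM (log2 ratio -4.49), the chemokine Ccl8 at 2506 against 116 (-4.43). The protease inhibitor Serpina3g stood at 103 against 5.17 (-4.31), the channel gene Calhm6 at 139 against 7.60 (-4.19) and the monocyte gene Adgre4 at 73.6 against 5.17 (-3.83). Gbp2b had 1 UMI in AKT1.MYC (50.9 against 0.0784 CPM; log2 ratio -9.34, -14.65 to -6.86). The class II subunit H2-Aa (ENSMUSG00000036594; chromosome 17, 34282744 to 34287823) stood at 8325 against 806 CPM, its chaperone Cd74 at 27119.8 against 2769 and the transactivator Ciita at 44.7 against 2.51. In the other direction, arginase 1, Arg1 (ENSMUSG00000019987; chromosome 10, 24915221 to 24927484), which depletes arginine, stood at 8.70 against 515 CPM (5.89), the neutrophil attractant Cxcl3 at 1.12 against 65.1 (5.86), the matrix gene Thbs1 at 18.4 against 613 (5.05). The decoy receptor Il1r2 stood at 2.32 against 55.9 (4.59), the apoptotic cell bridge Mfge8 at 8.07 against 147 (4.19), the metalloprotease Adam8 at 12.6 against 193 (3.93) and the growth factor Vegfa at 4.39 against 60.1 (3.77). AA467197 (4.79 against 225 CPM), Rgcc (4.07 against 66.7) and the adhesion gene Jaml (5.35 against 74.4) were higher in AKT1.MYC too. In the Kupffer-like clusters alone, clusters 14 and 24, the ratios were smaller for Arg1 (2.73), Rgcc (2.33) and AA467197 (4.002) and larger for Adam8 (5.52) and Vegfa (4.88), and that of Cxcl3, with 0 UMIs in NRAS.MYC.ND, was at least 2.42. With free RNA subtracted they were 7.39 for Arg1, 6.53 for Cxcl3 and at least 8.63 for Mfge8. Thinned to 1005 UMIs, with 98 and 344 cells left out, 9.88% against 0.841% of cells had Cxcl9 (T, NK and ILC cells, 1.15% against 1.56%) and 1.00% against 13.4% had Arg1 (1.09% against 1.56%). The AKT1.MYC share of Cxcl9 and the NRAS.MYC.ND share of Arg1 did not exceed that free RNA level. Not thinned, the shares were 20.7% against 1.44% and 4.89% against 24.6%. Median depth before thinning was 6644 against 2870 UMIs in this class and 2795 against 2723 in T, NK and ILC cells.

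**Figure D3:**
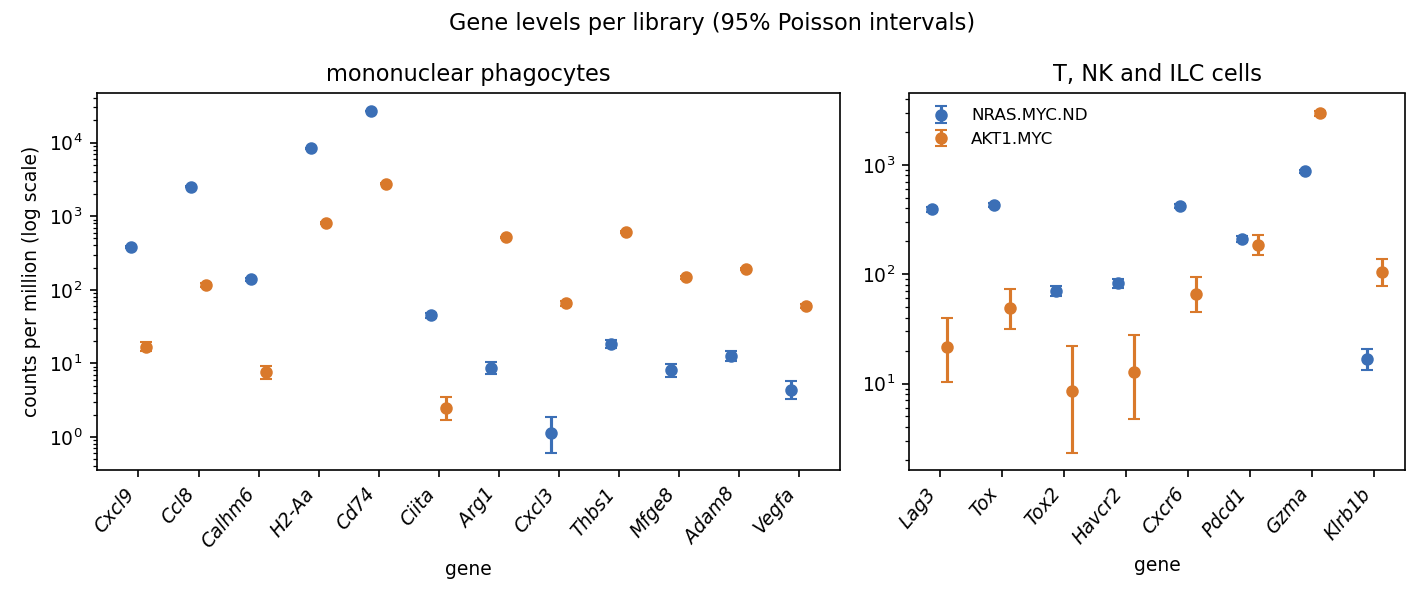
Levels of 12 genes in mononuclear phagocytes and 8 genes in T, NK and ILC cells in CPM (log axis), with bars for exact 95% Poisson intervals of counting error. Arg1 stood at 8.70 against 515 CPM and Cxcl9 at 379.6 against 16.9 CPM in mononuclear phagocytes, and Lag3 at 390.2 against 21.4 CPM in T, NK and ILC cells.

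Macrophage programmes followed these genes. All but 1 of 11 class II presentation members were higher in NRAS.MYC.ND (median -2.52, interval -2.63 to -2.44), at percentile 0 of random lists. The Kupffer identity list, whose Clec4f (762 against 80.1 CPM), Vsig4 (835 against 136), Timd4 (52.9 against 3.76) and Cd5l (3234 against 251) are naming markers, had 13 of 15 members higher in NRAS.MYC.ND (median -2.71), the complement gene C6 (79.1 against 5.25) included. Cells with UMIs of at least 2 of 5 Kupffer genes were 18.96% (17.00 to 21.04) against 5.29% (4.44 to 6.24) of thinned cells (not thinned, 30.3% against 8.80%), and 0.543% and 0 of 128 T, NK and ILC cells, the latter allowing up to 2.34%. Lipid-associated macrophage genes leaned to AKT1.MYC (6 members against 1; median 0.75), with Gpnmb (191 against 586 CPM), Trem2 (437 against 1045) and the protease Ctsl (439.9 against 1790.2) higher there and lipoprotein lipase, Lpl (1041 against 339), in NRAS.MYC.ND. Spp1 (ENSMUSG00000029304; chromosome 5, 104435118 to 104441050) stood at 201 against 5833 CPM in phagocytes but also at 404 against 3542 CPM in T, NK and ILC cells and 11809 against 25809 CPM in epithelial cells, so free RNA made up an unknown part of it. Of 14 measured inflammatory genes, 7 were higher in AKT1.MYC, 1 in NRAS.MYC.ND and 6 in neither (median 1.09), with Cxcl2 (312 against 3214), Il1b (381 against 1299) and Ptgs2 (6.63 against 43.5) higher in AKT1.MYC and Il18 (126 against 32.99) in NRAS.MYC.ND. The alternative activation list was split (5, 3 and 7 in neither; median -0.06), with Il10 (12.1 against 40.7), Stab1 (101 against 289.9) and Chil3 (569 against 1197) higher in AKT1.MYC. Hypoxia genes had 9 of 14 members higher in AKT1.MYC and 0 in NRAS.MYC.ND (median 1.45), with Egln3 (0.399 against 19.4) and Hilpda (36.6 against 329) in front, and glycolysis genes 4 and 0 (median 0.65), with Pgk1 (169.5 against 476). The classes compared lay in clusters 4, 14 and 20 of NRAS.MYC.ND and clusters 0, 7 and 24 of AKT1.MYC. The Kupffer-like clusters alone, 14 and 24, gave class II a median of -1.41 (-2.42 to -1.30), Kupffer identity -1.56 (-1.69 to -1.42), lipid-associated genes 0.73 (0.62 to 0.79) and hypoxia 0.75 (0.31 to 1.28). Cluster 14 held 377 and 1 cells and cluster 24 held 2 and 188, so 1 library's cluster was set against the other's. Clustering phagocytes and neutrophils again named 415 NRAS.MYC.ND cells (21.8%) and 9 AKT1.MYC cells (0.229%) Kupffer-like. The label of cluster 24 thus does not show that its AKT1.MYC cells were Kupffer cells.

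In neutrophils, Il1a (3.19 against 133 CPM; log2 ratio 5.38, 3.51 to 8.44), the alarm cytokine, and Prnp (7.98 against 233, 4.87) were among the most different genes. Hilpda (30.3 against 856), Vegfa (12.8 against 90.8), Cxcl2 (4919 against 23541), Cxcl3 (47.9 against 301) and the arginase Arg2 (75.01 against 199.6) were higher in AKT1.MYC, while Cd84 (404 against 116) was higher in NRAS.MYC.ND. Members higher in AKT1.MYC, in NRAS.MYC.ND and in neither numbered 6, 0 and 6 for hypoxia (median 1.10), 7, 1 and 7 for inflammatory activation (1.06) and 5, 1 and 8 for suppressive and tumour genes (0.55). The median of all genes in this class was 0.53, so list medians near that value show no difference of their own. Camp (6889.8 against 116 CPM), a granule gene and naming marker, was higher in NRAS.MYC.ND, where cluster 17 held the class, than in AKT1.MYC, where cluster 2 held it. In conventional DCs (clusters 18 and 26), Ccl17 (17.1 against 308 CPM), which attracts CCR4-bearing T cells, the growth factor Areg (2.73 against 55.05) and Trem1 (5.07 against 67.3) were higher in AKT1.MYC. Dnase1l3 (147 against 4.08; log2 ratio -5.17, -8.22 to -3.30) and Serpina3g (81.8 against 2.04; -5.33, -10.64 to -2.83) were higher in NRAS.MYC.ND. Fscn1 (211 against 4.08; -5.69, -8.74 to -3.83) and Il12b (65.1 against 2.04; -4.996, -10.31 to -2.498), markers of migratory DCs, were higher in NRAS.MYC.ND. Class II genes of DCs were near equal, with H2-Aa at 15665 against 13152 CPM and a list median of -0.25 (-0.34 to -0.22).

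The second comparison asked how the epithelial cells differed between the libraries. Hepatocyte-lineage cells were 6.78% (6.14 to 7.47) against 1.85% (1.59 to 2.14) of kept cells, whereas cholangiocyte-like cells, named by bile duct markers, were 0.781% (0.568 to 1.05) against 20.2% (19.4 to 21.01). Cluster 12, with 11 of the 44 NRAS.MYC.ND and 428 AKT1.MYC cells of that class, had cycling genes as its top 10. Its 11 NRAS.MYC.ND cells held Nras at 1399 CPM, against 1588 CPM in hepatocyte-lineage cells, and Krt19 at 90.7 CPM. Cluster 16, with 321 AKT1.MYC cells, was named on 3 markers, the minimum. The label thus does not show that all these cells were duct-like. As log2 ratios of shares, the hepatocyte-lineage value of -1.87 moved to -4.12 at a mitochondrial limit of 40% and -1.55 with each library clustered alone. The cholangiocyte-like value of 4.69 moved to 3.44 with each library clustered alone. Epithelial cells together were 7.56% against 22.04% of kept cells. In the hepatocyte-lineage class, a single cluster shared by both libraries (382 and 174 cells; median depths 8152 and 1903 UMIs), the steroid enzyme Akr1c18 stood at 363 against 2.15 CPM (-7.40, -10.44 to -5.54), the cell-cycle inhibitor Cdkn2a at 364 against 5.38 (-6.08), the retinol enzyme Rdh16f2 at 58.4 against 1.08 (-5.76, -11.07 to -3.27). The mucosal chemokine Cxcl17 stood at 99.9 against 2.15 (-5.54, -8.59 to -3.68), the sulfotransferase Sult2a2 at 72.7 against 2.15 (-5.08, -8.13 to -3.22), the liver cancer marker Gpc3 at 217 against 6.45 (-5.07), Cxcl9 at 227 against 7.53 (-4.91) and the trefoil peptide Tff3 at 133 against 5.38 (-4.63). Cyp2a4, a steroid hydroxylase, stood at 209 CPM in NRAS.MYC.ND and 0 UMIs in AKT1.MYC, at least 64.7-fold lower there. With cells thinned to equal depth, Akr1c18, Cdkn2a, Rdh16f2, Cxcl17 and Cyp2a4 had 0 UMIs left in AKT1.MYC, so thinning gave only limits, which allow these ratios. Higher in AKT1.MYC were the calcium-binding S100g (16.8 against 712 CPM, 5.40), creatine kinase Ckb (11.5 against 447, 5.28), the galectin Lgals2 (4.40 against 162, 5.20), Aldh1a7 (6.89 against 125, 4.18), Fam25c (23.5 against 355, 3.91), the acute-phase Orm2 (6.32 against 91.4, 3.86). So were the stress regulator Nupr1 (5.17 against 64.5), the folate enzyme Mthfd2 (6.51 against 70.98), the glucose-releasing G6pc (6.70 against 72.1) and the antioxidant Gpx3 (20.5 against 161). Over all epithelial cells, genes higher in AKT1.MYC included Wfdc18 (27.6 against 3313 CPM), of the WAP peptidase inhibitor family, the receptor subunit Gabrp (1.36 against 148) and Tmem252 (2.38 against 257). Genes higher in NRAS.MYC.ND included the urea-cycle gene Otc (126 against 0.357) and Akr1c18 (324 against 0.446).

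Pathway lists downstream of the injected oncogenes went in different directions. MAPK pathway output, downstream of RAS, had 6 of 17 members higher in NRAS.MYC.ND hepatocyte-lineage cells and 2 in AKT1.MYC (median -0.97, interval -1.24 to -0.51), percentile 0.01. The median was -2.09 with equal weight per cell and -0.39 with cells thinned, which left 8 measured members. Members included the feedback inhibitor Spry2 (-2.94, -8.27 to -0.38), Etv4 (41.2 against 12.9 CPM) and Spred2 (-1.61) on one side and Ier3 (287 against 1334) on the other. In epithelial cells its median was -0.95, with Etv4 at 39.6 against 3.57 CPM. Fatty acid synthesis, an AKT and mTORC1 output, had 4 members higher in AKT1.MYC, among them Scd1 (279.5 against 1085), Me1 (1.87) and Fasn (23.7 against 63.5), and 1 in NRAS.MYC.ND, Mlxipl (-2.49), with a median of 0.24 at percentile 75.7 (epithelial 0.20). Glycolysis had 10 of 17 members higher in AKT1.MYC and 0 in NRAS.MYC.ND (median 1.07, percentile 100; epithelial 0.80), with Hk2 (1.91 against 15.1) and Pgk1 (238 against 1045). Cholesterol synthesis had 6 and 0 (median 0.78; epithelial 0.88), with Fdps (59.9 against 166) and Hmgcs1 (1.41), and MYC targets and ribosome biogenesis 7 and 0 (median 0.66; epithelial 0.56), with the polyamine genes Srm (49.8 against 154) and Odc1 (1.44). Hypoxia genes were higher in AKT1.MYC (6 and 0; median 0.49; epithelial 1.06). The p53 target and senescence list was lower (1 and 4; median -0.53; epithelial -0.502), with Cdkn2b (107 against 7.53) and Mdm2 (-1.18) beside Cdkn2a.

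Liver function genes depended on which epithelial cells were counted. In hepatocyte-lineage cells, secreted liver proteins, many of them naming markers, had a median of -0.57, with Alb at 16855 against 3506 CPM, cytochrome P450 and xenobiotic genes -0.22, urea cycle and gluconeogenesis -0.22 and bile acid genes -0.15, while in all epithelial cells the medians were -3.90, -3.02, -2.94 and -2.87. The fetal genes Afp (223 against 12.9 CPM) and H19 (1803 against 143) were higher in NRAS.MYC.ND hepatocyte-lineage cells, with an oncofetal and progenitor list median of -0.11 (epithelial 0.62). In epithelial cells that list was split, with 6 members higher in AKT1.MYC, 6 in NRAS.MYC.ND and 4 in neither. Acute phase genes had a median of 0.53 (epithelial -1.78), with the iron hormone Hamp at 289 against 1808 CPM, and beta-catenin targets 0.65 (-0.01 to 1.27) over 7 measured members, which turned to -0.499 with equal weight per cell (epithelial -0.27). Tumour chemokines and cytokines were split (5 and 2; median 0.502; epithelial 0.25), with the monocyte attractant Ccl2 (18.00 against 97.9 CPM) higher in AKT1.MYC and Cxcl9 in NRAS.MYC.ND. The list also counts Cxcl2 (26.99 against 322) and Ccl5 (306 against 16.1), which free RNA could bring to these levels. Cxcl2 stood at 320.4 CPM in AKT1.MYC endothelial cells and Ccl5 at 306 CPM in NRAS.MYC.ND neutrophils.

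Interferon response genes were lower in AKT1.MYC in 8 of 9 compared classes, of which the epithelial class includes the hepatocyte-lineage cells. The medians were -1.62 (-1.77 to -1.51) in mononuclear phagocytes (percentile 0), -1.75 (-1.98 to -1.47) in epithelial cells, -1.27 (-1.73 to -0.96) in hepatocyte-lineage cells, -1.42 (-1.56 to -1.27) in endothelial cells, -1.37 (-1.70 to -1.02) in neutrophils, -1.34 (-1.70 to -0.999) in conventional DCs, -1.14 (-1.49 to -0.64) in T, NK and ILC cells and -1.12 (-1.42 to -0.85) in fibroblasts. In erythroid cells it was 0.68 (-0.36 to 1.26) over 9 measured members. The GTPase Iigp1 stood at 73.2 against 12.6 CPM in phagocytes (a difference that turned to a log2 ratio of 1.90 with free RNA subtracted), 371 against 14.1 in epithelial and 951 against 187 in endothelial cells. In the CD8 gate the median was -0.26 (-0.65 to 0.17), and in the Kupffer-like clusters -0.42 (-0.66 to -0.30). Class I presentation followed, with -0.93 in phagocytes, -0.81 in hepatocyte-lineage, -0.67 in epithelial and -1.49 in endothelial cells, where the class I light chain B2m stood at 2766 against 898, 2044 against 568, 2016 against 505 and 2646 against 626 CPM. In clusters that both libraries share, class I medians were -1.01 (-1.25 to -0.79) and -1.20 (-1.43 to -1.02) in endothelial clusters 9 and 11 and -0.33 (-0.66 to -0.14) in cluster 22. In the Kupffer-like clusters the class I median was -0.42 (-0.58 to -0.31). These are not shared: cluster 14 held 377 and 1 cells and cluster 24 held 2 and 188. Class II in endothelial cells had a median of -1.55. With free RNA subtracted it turned to 4.04 over 4 members, all of them with 0 UMIs in 1 library, so the value is a limit.

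**Figure D4:**
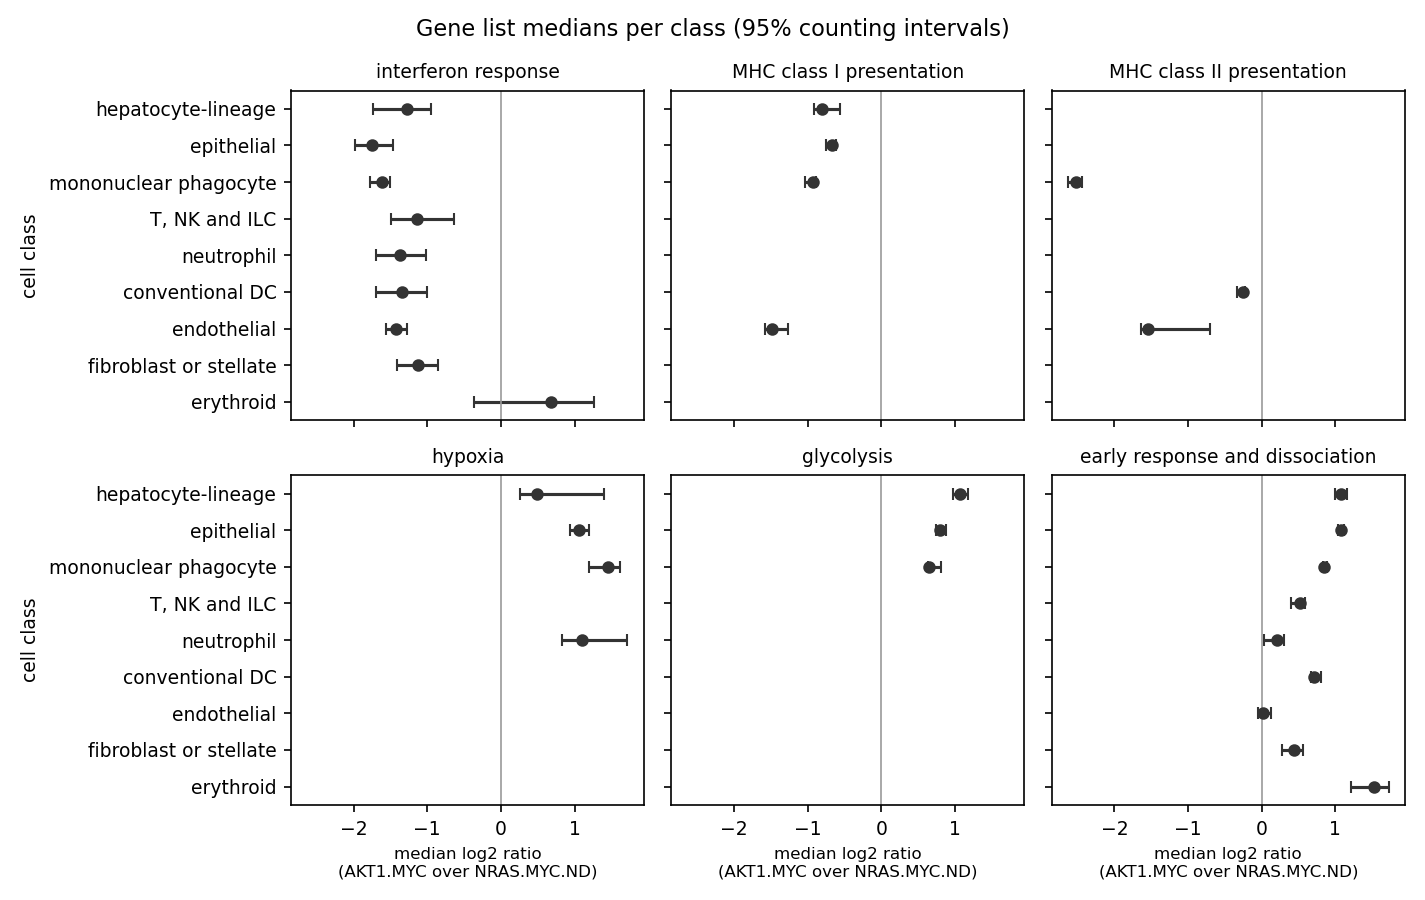
Median log2 ratio (AKT1.MYC over NRAS.MYC.ND) of 6 gene lists in the compared cell classes, with bars for 95% intervals of counting error. Interferon response medians lie below 0 in 8 classes, from -1.75 to -1.12, and at 0.68 in erythroid cells.

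Endothelial cells of AKT1.MYC had lower sinusoidal genes, the signature of the liver's fenestrated vessels. Clec4g (1225 against 96.9 CPM) and Dnase1l3 (1095 against 82.5), both naming markers, the scavenger receptor Stab2 (928 against 234, a naming marker) and the enzymes Npl (83.3 against 5.04) and Ces2e (74.9 against 5.67) were higher in NRAS.MYC.ND, as was Pcp4l1 (58.5 against 1.26). Sinusoidal members numbered 13 of 15 higher in NRAS.MYC.ND (median -2.04). Capillary and tumour endothelium genes had 7 members higher in AKT1.MYC and 1 in NRAS.MYC.ND (median 0.52): the angiogenic ligands Apln (21.6 against 143) and Pgf (1.52 against 38.7) and Vwf (168 against 645) against the receptor Kdr (2039 against 673). Ptn had 2 UMIs in NRAS.MYC.ND (0.253 against 74.3 CPM; log2 ratio 8.20, 6.33 to 11.25), and Igfbp5 (16.3 against 311), the peptide genes Nts (19.2 against 265) and Npy (7.20 against 88.1) were also higher in AKT1.MYC. Most AKT1.MYC endothelial cells lay in cluster 11 and most NRAS.MYC.ND ones in clusters 9 and 19. Fibroblasts were 0.941% (0.705 to 1.23) against 9.27% (8.69 to 9.87) of kept cells, 53 and 871 cells. Of the latter, 567 lay in cluster 6, with a median of 916 UMIs, the platelet gene Ppbp first among its markers and the phagocyte gene C1qa at 1274 CPM. The log2 ratio of shares moved from 3.30 to 2.17 with each library clustered alone. The matrix and contractile list had 8 members higher in AKT1.MYC and 1 in NRAS.MYC.ND (median 0.90), with the protease inhibitor Timp1 (105 against 1564 CPM) and collagen Col1a1 (1412 against 7501, a naming marker) against Dcn (8531 against 2614, a naming marker).

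Checkpoint ligand medians lay between -0.21 in conventional DCs and 0.48 in neutrophils, with -0.16 in phagocytes, -0.15 in hepatocyte-lineage, 0.00 in epithelial and 0.04 in endothelial cells. The PD-1 ligand Cd274 stood at 52.2 against 22.5 CPM in phagocytes and 6.98 against 1.55 in epithelial cells, its relative Pdcd1lg2 at 6.38 against 40.7 in neutrophils, and the TIGIT ligand Pvr at 13.1 against 39.96 in phagocytes. Proliferation medians were 1.20 in hepatocyte-lineage cells, with Rrm2 (2.57) and Mki67 (-1.23) apart, 0.28 in epithelial cells (-0.80 at a mitochondrial limit of 10%), 0.66 in phagocytes (0.37 to 2.90 over the alternatives, the latter with free RNA subtracted and 9 of 14 members at 0 UMIs in 1 library), -0.63 in T, NK and ILC cells, 1.504 in neutrophils, -0.41 in DCs, 0.23 in endothelial cells, 1.32 in fibroblasts (-0.30 with cells thinned, over 4 members) and -2.82 in erythroid cells. Of 16 early response and dissociation genes, which tissue handling induces, 9 were at least 2-fold higher in AKT1.MYC in hepatocyte-lineage (median 1.08), 9 in epithelial (1.08) and 11 in erythroid cells (1.52). Fewer passed in mononuclear phagocytes (4; 0.84), conventional DCs (6; 0.71), T, NK and ILC cells (5; 0.52) and fibroblasts (3, and 1 higher in NRAS.MYC.ND; 0.44). The medians were 0.02 in endothelial cells and, below the median of all genes there, 0.21 in neutrophils. In clusters that both libraries share, the medians were 0.35 (0.22 to 0.505) in endothelial cluster 9, 0.51 (0.42 to 0.66) in endothelial cluster 11, -0.17 (-0.27 to 0.02) in NK cell or ILC1-like cluster 22 and 0.00 (-0.07 to 0.14) in unnamed cluster 25. In the Kupffer-like clusters the median was 1.17 (1.11 to 1.22), above that of the phagocyte class, so class values also depend on the mix of clusters.

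Free RNA differed between the libraries. The liver gene Apoa1 stood at 414 against 18.3 CPM in mononuclear phagocytes and 715 against 34.2 CPM in T, NK and ILC cells, and the collagen Col3a1 at 2.48 against 122 and 4.45 against 154 CPM. Before any subtraction, the marker panel of other cell types had medians of -0.63 in hepatocyte-lineage, -2.15 in epithelial, -1.96 in phagocyte, -0.19 in T, NK and ILC, -1.74 in neutrophil, -1.24 in DC, -1.16 in endothelial, -2.01 in fibroblast and 0.31 in erythroid cells. Of the library and animal checks, the Y-linked Ddx3y stood at 83.7 against 52.9 CPM and Xist at 0.158 against 0.0829 CPM, the same male pattern in both libraries, and the list median was -0.66. B cell activation genes were not compared, since AKT1.MYC held 36 B and plasma cells, below the minimum of 50.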

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

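Tests of cell states and clusters within classes, and the thinning of every barcode to 500 UMIs, were chosen after the result was seen, the other tests of this part before it, and the genes shown for unnamed clusters were picked after seeing them.

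Cells outside the named classes carried signals of their own. Unnamed cluster 25 led in genes of neutrophil precursors: Elane (ENSMUSG00000020125; GRCm38 chromosome 10, 79886247 to 79888215), the neutrophil elastase gene, stood at 70.8 CPM (55.1 to 89.6) in its 65 NRAS.MYC.ND cells, against 0.810 CPM in named cells. In its 78 AKT1.MYC cells it stood at 1279.5 CPM (1211 to 1350.5), against 1.87 CPM. In sums over the cluster, other granule genes stood at 74.9 against 323 CPM (Mpo), 169 against 880.2 CPM (Prtn3) and 34.9 against 226 CPM (Ctsg). The cycling gene Mki67 stood at 322 against 283 CPM. The macrophage gene C1qa stood at 1087 against 3830 CPM, and at 1728 against 1419 CPM in the cells of other clusters. Markers of conventional DCs were also higher in this cluster, which stayed unnamed because neutrophil genes were among its top 10. Sums do not show that 1 cell type held all these genes. Its interferon response median of -1.54 (-2.08 to -1.26) may thus compare different mixtures.

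Unnamed cluster 1 held 17.2% (16.4 to 17.9) of kept AKT1.MYC cells, 1613 cells with a median of 655 UMIs, and 1 NRAS.MYC.ND cell. Mitochondrial ribosomal RNA was high in it: mt-Rnr2 at 9089.9 CPM against 2648 in the other AKT1.MYC cells, and mt-Rnr1 at 5033 against 964 CPM. Abundant genes of epithelium, macrophages and neutrophils were all present, within 2-fold of the other AKT1.MYC cells, with Krt19 at 632 against 719.7 CPM, C1qa at 2253 against 1444 and S100a8 at 488 against 909. These cells were counted among kept cells but in no class.

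T, NK and ILC cells were a smaller share of immune cells in AKT1.MYC. Loss to the filters or to other clusters was argued against by all deposited barcodes, of which 30.1% against 1.29% had UMIs of at least 2 T receptor genes, 23.3-fold (19.6 to 27.9) more in NRAS.MYC.ND. Of these barcodes 453 and 36 lay outside the class, where free RNA can also bring T receptor genes. The share is of all barcodes, not of immune cells. Loss of barcodes under 500 UMIs before deposit could not be tested. Lower depth was argued against by the same share with barcodes of at least 2000 UMIs thinned to 2000 (4828 of 6312 and 4973 of 10766 barcodes), 17.7-fold (14.1 to 22.5), and with every barcode thinned to 500, 50.8-fold (37.6 to 70.2). With 1 library per group, a lower yield of T cells from the piece of tissue taken or its dissociation cannot be told apart from fewer T cells in the tumours. The oncogene pair, the plasmid amounts and the animals used also stay open, untested. The number of animals per library is not given in the sources used here.

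Interferon response genes were lower in AKT1.MYC in 8 compared classes. Free RNA of 1 cell type as the only source in every class was argued against by the ratio of Cxcl9 to Iigp1 UMIs in NRAS.MYC.ND. It differed 220.3-fold between mononuclear phagocytes and fibroblasts, the latter with 2 Cxcl9 UMIs, and 17.5-fold among classes with at least 30 UMIs of each gene. This cannot decide for single classes, since a class that makes 1 of the 2 genes itself also changes the ratio. The ratio lay between 0.296 and 0.95 in hepatocyte-lineage, T, NK and ILC, neutrophil and endothelial cells, against 5.18 in mononuclear phagocytes and 4.44 in conventional DCs. Iigp1 in mononuclear phagocytes also reversed with free RNA subtracted. Median of ratios scaling left the median below -0.5 in 8 of 8 classes, which argued against scaling to the class total. A different mix of clusters within the endothelial class as the whole cause was argued against by 2 of 2 clusters that both libraries share, with medians of -1.19 and -1.15. Cell states within these clusters were not tested. In cluster 11, Mki67 stood at 441 against 43.8 CPM and median depth was 1163 against 4074 UMIs. The hepatocyte-lineage class is 1 cluster, whose value is that of the class, so different cell states within it cannot be told apart from a lower response. Within mononuclear phagocytes, where Kupffer-like clusters alone gave -0.42 (-0.66 to -0.30), and within T, NK and ILC cells, where the CD8 gate gave -0.26 (-0.65 to 0.17) and NK cell or ILC1-like cluster 22 -1.09 (-1.60 to -0.46), different cell states cannot be told apart from a lower response of the same cells, since these intervals reach both sides of -0.5. The oncogene pair, the plasmid amounts and the animals used stay open, untested.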

How the results depend on the processing

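Comparisons in Kupffer-like clusters, neutrophil-like sub-clusters, cells gated by T receptor, Cd8, Cd4, NK or Kupffer genes and all epithelial cells, and those with 0 counts kept at their limit, were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because each group has 1 library, and none of these values has a test. The share of T, NK and ILC cells among immune cells, a log2 ratio of -3.42, lay between -3.46 and -3.27 over its alternatives, and that of neutrophils between 1.78 and 1.92. Over all deposited barcodes, as over all kept cells, Nras was higher in NRAS.MYC.ND, and Akt1 and Myc (0.58) in AKT1.MYC. Myc was lower in AKT1.MYC in hepatocyte-lineage and in pooled epithelial cells, but higher there in cholangiocyte-like cells.

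The share of epithelial cells kept its direction but moved from 1.54 to 0.62 at a mitochondrial limit of 40%, 1.20 without doublet removal, 1.38 at Leiden resolution 0.5, 1.22 at resolution 2.0, 1.11 with each library clustered alone and 1.15 with 2 times as many variable genes. Of immune cells, conventional DCs moved from -2.07 to -1.24 with at least 1000 UMIs and 500 genes. They reversed to 0.46 with each library clustered alone, where B and plasma cells moved from -3.27 to -1.77 and mononuclear phagocytes from 0.81 to 0.59. All immune cells moved from -0.72 to -0.40 with at least 1000 UMIs and 500 genes, -0.80 at resolution 2.0 and -0.81 with 2 times as many variable genes. The cause was not tested.

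Secreted liver proteins in epithelial cells moved from -3.90 to -3.96 with median of ratios scaling, -3.99 with upper quartile scaling, -3.38 with equal weight per cell, -3.40 thinned and -3.83 at a mitochondrial limit of 10%. MHC class II genes in mononuclear phagocytes moved from -2.52 to -2.65 with equal weight per cell, -2.88 thinned and -1.41 in Kupffer-like clusters alone. Interferon response genes there moved from -1.62 to -0.42 in Kupffer-like clusters alone. Exhaustion and checkpoint receptors lay between -1.78 and -1.34. With free RNA subtracted, the reversed values were 4.04 for class II genes in endothelial cells and 1.90 for Iigp1 in mononuclear phagocytes. For the marker panel they were 0.0862, 0.12, 1.91 and 1.35 in mononuclear phagocytes, conventional DCs, endothelial cells and fibroblasts. These medians rest on 3 to 5 members, of which 2 to 4 had 0 UMIs in 1 library. The reversed values were at least 4.72 and 4.92 for Apoa1 in mononuclear phagocytes and T, NK and ILC cells, where Apoa1 set the amount subtracted. With cells thinned, proliferation genes in fibroblasts reversed to -0.30 and the marker panel in hepatocyte-lineage cells to 0.81; apart from Apoa1, the cause was not tested. Counting every result under every alternative, 793 stayed the same, 217 moved and 7 reversed for gene lists. For named genes, 1054 stayed the same, 378 moved and 3 reversed, and 121, 30 and 1 for class shares. Of 104 list medians, 27 took both signs over the alternatives, 10 of them at least 0.5 from 0 in the values of the report, so their direction depends on the setting. At least 1 alternative moved 41 of the list medians by 0.5 or more. Of 203 ratios of named genes, 152 left their counting interval under some alternative and 73 moved by 1 or more. Ratios at 0 UMIs in 1 library are limits and counted as moved only where they shut out the interval, which none of 14 such ratios in thinned cells did.

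Median of ratios scaling shifted the median of all genes by -0.13 in hepatocyte-lineage, -0.37 in neutrophil, 0.21 in fibroblast and -0.81 in erythroid cells. Upper quartile scaling shifted it by -0.40 in neutrophil, 0.11 in conventional DC, 0.13 in endothelial, 0.11 in fibroblast and -0.33 in erythroid cells. A mitochondrial limit of 10% left under 50 NRAS.MYC.ND fibroblasts and gave no value for that class. Depth limits genes of few UMIs, such as those with 1 to 3 UMIs in 1 library, to wide intervals.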

Other observations

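Tests of the epithelial clusters were chosen after the result was seen, and the genes of the next 2 paragraphs were picked by hand from the full tables, outside the naming rule, after their values were seen.

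Ligands of receptors on T cells and phagocytes differed by cell class. The ecto-enzyme Nt5e, which makes adenosine, stood at 0.799 against 10.97 CPM in mononuclear phagocytes and 1.14 against 5.04 in endothelial cells but 12.8 against 12.8 in epithelial cells, and the 4-1BB ligand Tnfsf9 at 4.95 against 21.2 in mononuclear phagocytes. The LAG3 ligand Fgl1, a hepatocyte product, stood at 188 against 219 CPM in hepatocyte-lineage cells and 167 against 14.9 in all epithelial cells. The phagocytosis inhibitor Cd47 was higher in NRAS.MYC.ND endothelial cells (716 against 343 CPM) and stood at 267 against 311 in hepatocyte-lineage cells, and Cd274 stood at 12.5 against 1.89 CPM in endothelial cells. Cxcl16, the ligand of Cxcr6, was higher in AKT1.MYC in hepatocyte-lineage (52.3 against 109) and epithelial cells (68.4 against 192) but lower in mononuclear phagocytes (464 against 360.3), where it was highest, and endothelial cells (178 against 85.6), and the neutrophil attractant Cxcl5 stood at 3.74 against 34.7 CPM in epithelial cells.

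Among hand-picked stress genes, Atf3 was higher in AKT1.MYC in epithelial (552 against 2717 CPM), mononuclear phagocyte (716 against 2337) and endothelial cells (125 against 659), and the heat-shock gene Hspa1b in epithelial cells (6.64 against 40.1) and mononuclear phagocytes (27.2 against 98.6). Zfp36, which destabilises inflammatory messenger RNA, was higher in NRAS.MYC.ND neutrophils (3002 against 1063) and endothelial cells (433 against 194), and Fos in NRAS.MYC.ND neutrophils (9161 against 4061). AA467197, a small mitochondrial protein gene, was higher in AKT1.MYC in endothelial cells (5.68 against 128 CPM), conventional DCs (56.9 against 518) and neutrophils (148 against 1095), with 6.19 against 49.2 CPM in T, NK and ILC cells. Mesothelial cells numbered 32 and 4 and erythroid cells 74 and 117.

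Epithelial cells were mostly hepatocyte-lineage in NRAS.MYC.ND and mostly cholangiocyte-like in AKT1.MYC. Akt1 in cholangiocyte-like clusters 3 and 12 of AKT1.MYC stood at 269 CPM, against 96.3 in cluster 21, 169 in cluster 16 and 175 in endothelial cells of that library. It was 2.79-fold that of cluster 21 but 1.54-fold (1.41 to 1.68) that of endothelial cells. By the Akt1 level, bile duct cells without the injected Akt1 thus cannot be told apart from cells that carried it. Whether that plasmid is human or mouse is not given in the sources used here. Myc, also injected, stood at 123 CPM in cluster 3 and 92.5 in cluster 12 of AKT1.MYC. In the same library it stood at 37.7 CPM in cluster 21, 53.4 in cluster 16 and 30.8 in endothelial cells. Whether the higher Myc came from the plasmid was not tested. In cluster 21, which both libraries share, Nras in NRAS.MYC.ND was 0.642-fold (0.467 to 0.863) and Akt1 in AKT1.MYC 0.551-fold its level in endothelial cells. Neither was above that level, the outcome set for bile duct cells that carried no injected oncogene. Nras stood at 88.1 CPM in cluster 21 of NRAS.MYC.ND, against 1588 CPM in its hepatocyte-lineage cells. Myc stood at 11.5 against 37.7 CPM in cluster 21 and at 43.5 against 30.8 CPM in endothelial cells. These levels do not show that cluster 21 carried no plasmid, since only an unknown part of the transgene reads could map to the mouse loci. The oncogene pair, the plasmid amounts, the cell of origin and the animals used stay open, untested.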
